A study of Mus musculus with 12 samples.

How the data were processed

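RNA sequencing was done on 12 libraries of N2a cells, a mouse neuroblastoma line. The libraries fell into 3 groups of 4 by their labels: cells given brain-derived extracellular vesicles (BDEVs) of the SE group, cells given BDEVs of the CON group, and cells given vehicle. Extracellular vesicles are small membrane-bound particles that cells release. SE stands for status epilepticus, a prolonged seizure, as the title of the series gives it; the labels used here do not spell out CON. Per the labels' protocols, RNA was taken with a column kit and libraries were made from polyadenylated RNA with a kit that keeps the strand. The labels do not say whether the 4 libraries of a group came from separate cultures or separate vesicle preparations, so p-values measure only the spread between these samples, which may be technical.

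The deposited tables give FPKM per gene and library (fragments per kilobase of transcript, scaled to the mapped fragments of the library), made by the authors with TopHat2 and Cuffdiff on the mouse build mm9, per the submitters' processing notes, which give no versions. One table held the SE-BDEV and Vehicle libraries and the other the CON-BDEV and Vehicle libraries, with 24318 gene rows each, of which 100 held several gene names. For each of these comparisons a separate deposited table gives, per the file headers, the authors' group values in FPKM, a log2 fold change, a p-value and a q-value per gene from Cuffdiff. Over the genes with a group mean above 1 FPKM, 11328 for SE-BDEV and 11301 for Vehicle in the one table and 11329 for CON-BDEV and 11302 for Vehicle in the other, the group values equalled the mean of the library columns within 0.01%, except for 1 gene of the SE-BDEV group that was off by 3.17%. Lower genes were not compared. Annotation version, read filters and the strand setting of the counting are not given in the sources used here, so values of genes that overlap or have near-identical copies, ribosomal protein genes with processed pseudogenes among them, are uncertain.

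The same 4 Vehicle libraries stood in both tables. Over the 11350, 11309, 11292 and 11271 genes above 1 FPKM in Vehicle replicates 1 to 4, their columns differed between the tables by 1 factor per library that lay within 0.0335% of 1, with 4 to 7 genes per library off that factor by more than 0.01% and by at most 0.116%. The tables were therefore treated as being on 1 scale, and the Vehicle value was the mean of both. No library of the SE-BDEV or CON-BDEV group stood in both tables, so their scale could be checked only through the Vehicle columns.

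Library totals are not part of the deposited tables. Depth was estimated from the lowest nonzero FPKM values (up to 0.05) of genes with a transcript of 1500 to 8000 bases, on the reading that these stand for 1 fragment. Transcript lengths came from a newer mouse annotation than the one the authors used, so depths are approximate. They were 14000000, 13800000, 13000000 and 15500000 fragments for SE-BDEV replicates 1 to 4, 14400000, 12700000, 13900000 and 13800000 fragments for CON-BDEV replicates 1 to 4, and 16500000, 16200000, 15900000 and 15100000 fragments for Vehicle replicates 1 to 4. Over 11312 genes the median within-group SD of log2(FPKM + 1) was 0.0898 in SE-BDEV, 0.0739 in CON-BDEV and 0.0565 in Vehicle, and libraries of 1 group correlated across genes with r between 0.990 and 0.997.

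FPKM values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided). Genes with a mean of at least 1 FPKM over the libraries of the fit were tested, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. SE-BDEV and CON-BDEV were each compared with Vehicle within their own table, over 8 libraries. SE-BDEV was compared with CON-BDEV in a fit of all 12 libraries. Every adjusted p of a gene in the text comes from limma unless the authors' deposited table is named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

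Before the data were examined, 36 gene lists were fixed from textbook knowledge, and 32 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and fry was run as a rotation test of each list by itself. The lists included markers of other brain cell types, of which the astrocyte, oligodendrocyte, endothelial and forebrain neuron lists were tested; mitochondrially encoded genes (0 measured) and the microglia, red blood cell and choroid plexus lists (2, 1 and 4 measured) were not. As an addition after the data were seen, the mean log2(FPKM + 1) of a list per library was compared between groups of 4 with a two-sided exact permutation test, for which 0.0286 is the smallest p that 4 against 4 libraries allow.

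The genes named in the text were chosen by a rule set beforehand. For each comparison with Vehicle it took up to 10 genes each way with the largest change among those past the threshold whose treated libraries all lay on the same side of the Vehicle mean, and up to 4 members of each list with the smallest adjusted p. It also took the 5 genes each way with the largest mean change among those called in both comparisons and, for SE-BDEV against CON-BDEV, where too few genes passed, the 5 each way with the smallest p. Predicted loci, short RNA genes and rows with several names were left out, and fewer genes may be printed, in the order of the rule. Some genes that the rule picks are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

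The fits were tested on simulated data with 67, 67 and 66 genes changed by known amounts (log2 0.3, 0.5 and 1), drawn around the real gene means and spread. The changed genes were drawn from those with a mean of at least 5 FPKM. Genes varied independently, and all groups shared 1 spread per gene, unlike the real groups. The shares called may thus be lower for genes from 1 to 5 FPKM and in the real libraries. At a log2 change of 0.3, 80.6% of 67 changed genes were called for SE-BDEV against Vehicle (11273 genes), 91.0% of 67 for CON-BDEV against Vehicle (11283 genes) and 83.6% of 67 for SE-BDEV against CON-BDEV (11288 genes). At a log2 change of 0.5 the shares were 97.0%, 100% and 98.5% of 67 genes in the same order.

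Because both comparisons used the same Vehicle libraries, their overlap and correlation were set beside 100 simulations of unchanged groups against shared controls and beside all 6 ways of giving each comparison its own pair of Vehicle libraries. Alternatives fixed beforehand were another pseudocount, other filters on low values, median and quantile scaling, empirical Bayes without the trend or with robust settings, library weights, the replicate number as a block, 1 fit over all groups, a minimum fold change, the authors' own calls, and leaving out each library in turn. Alternatives added after the data were seen were leaving out the 2 SE-BDEV libraries that lay apart on the principal components and a comparison of all 8 BDEV libraries with Vehicle.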

Results

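Messenger RNA was profiled in N2a cells, a mouse neuroblastoma line, after treatment with extracellular vesicles derived from brain (BDEVs) or with vehicle. Each of the 3 groups, SE-BDEV, CON-BDEV and Vehicle, had 4 libraries. The SE group is named for status epilepticus, a prolonged seizure, and the title of the series puts the question whether this condition alters the function of brain vesicles. Estimated depths were 13000000 to 15500000 fragments per library for SE-BDEV, 12700000 to 14400000 for CON-BDEV and 15100000 to 16500000 for Vehicle. Every BDEV library but SE-BDEV replicate 4 was shallower than every Vehicle library. Expression is given in FPKM as the authors made it, and positions are on mm9 as in the deposited tables.

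Cells given SE-BDEVs expressed less of the machinery of cholesterol synthesis than cells given vehicle. Of 26 measured genes of cholesterol synthesis and other targets of the transcription factor SREBP2, 17 fell and 0 rose over all genes tested, and 23 fell adjusted over the list alone. The median log2 fold change of the list was −0.59, so that its median gene fell by 33.5%. Fdps, which makes farnesyl diphosphate (chromosome 3, 88897509 to 88905889), fell from 237 ± 6.85 FPKM (SD, n = 4) in Vehicle to 130 ± 19.8 FPKM (SD, n = 4) in SE-BDEV, a log2 fold change of −0.87 ± 0.09 (standard error; limma adjusted p = 0.00569). Lss, the lanosterol synthase (chromosome 10, 75994349 to 76024971), fell from 29.6 ± 1.69 to 17.3 ± 2.23 FPKM (SD, n = 4 each). Phosphomevalonate kinase (Pmvk; log2 fold change −0.66) and lanosterol demethylase (Cyp51; −0.53) had the same limma adjusted p as Fdps and Lss, 0.00569, the smallest of the comparison. Insig1, an endoplasmic reticulum protein that holds back SREBP activation and is itself induced by SREBP (chromosome 5, 28397951 to 28405202), had the largest fall among the named genes, from 63.2 ± 2.29 to 33.9 ± 8.93 FPKM (SD, n = 4 each; log2 fold change −0.92 ± 0.16, standard error; limma adjusted p = 0.0280). Msmo1, Nsdhl, Idi1 and Dhcr7, all enzymes of the pathway, fell with log2 fold changes from −0.71 to −0.67. Against other genes, camera gave the list an adjusted p of 1.6e-26, and of 0.20 with an estimated correlation. Fry, which tests the list by itself, gave an adjusted p of 0.0135.

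Genes of fatty acid synthesis moved the same way. Of 22 measured members of the fatty acid synthesis and SREBP1 target list, 9 fell and 0 rose in SE-BDEV over all genes tested, and 18 fell adjusted over the list alone, with a median log2 fold change of −0.29. Pnpla3, a lipid droplet protein (chromosome 15, 83998245 to 84019951), fell from 4.85 ± 0.358 to 2.37 ± 0.397 FPKM (SD, n = 4 each; log2 fold change −0.80 ± 0.09, standard error; limma adjusted p = 0.00703). Lpin1, a phosphatidate phosphatase (chromosome 12, 16542474 to 16596576), fell from 12.5 ± 0.577 to 7.05 ± 1.27 FPKM (SD, n = 4 each; log2 fold change −0.76 ± 0.10, standard error; limma adjusted p = 0.0122). The stearoyl-CoA desaturase gene Scd2 and the acetoacetyl-CoA synthetase gene Aacs fell with log2 fold changes of −0.59 and −0.68. Camera gave the list an adjusted p of 5.9e-20, with an adjusted p of 0.20 with an estimated correlation and 0.0135 in fry. Both lipid lists passed in camera with each of the 8 libraries left out in turn. The mean log2 level of the cholesterol list lay below every Vehicle library in 4 of 4 SE-BDEV libraries. It differed from Vehicle by −0.53 (SD 0.19 over the 4 SE-BDEV libraries and 0.03 over the 4 Vehicle libraries). The exact permutation p was 0.0286, the smallest the design allows, and 0.131 adjusted over the lists.

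**Figure D1:**
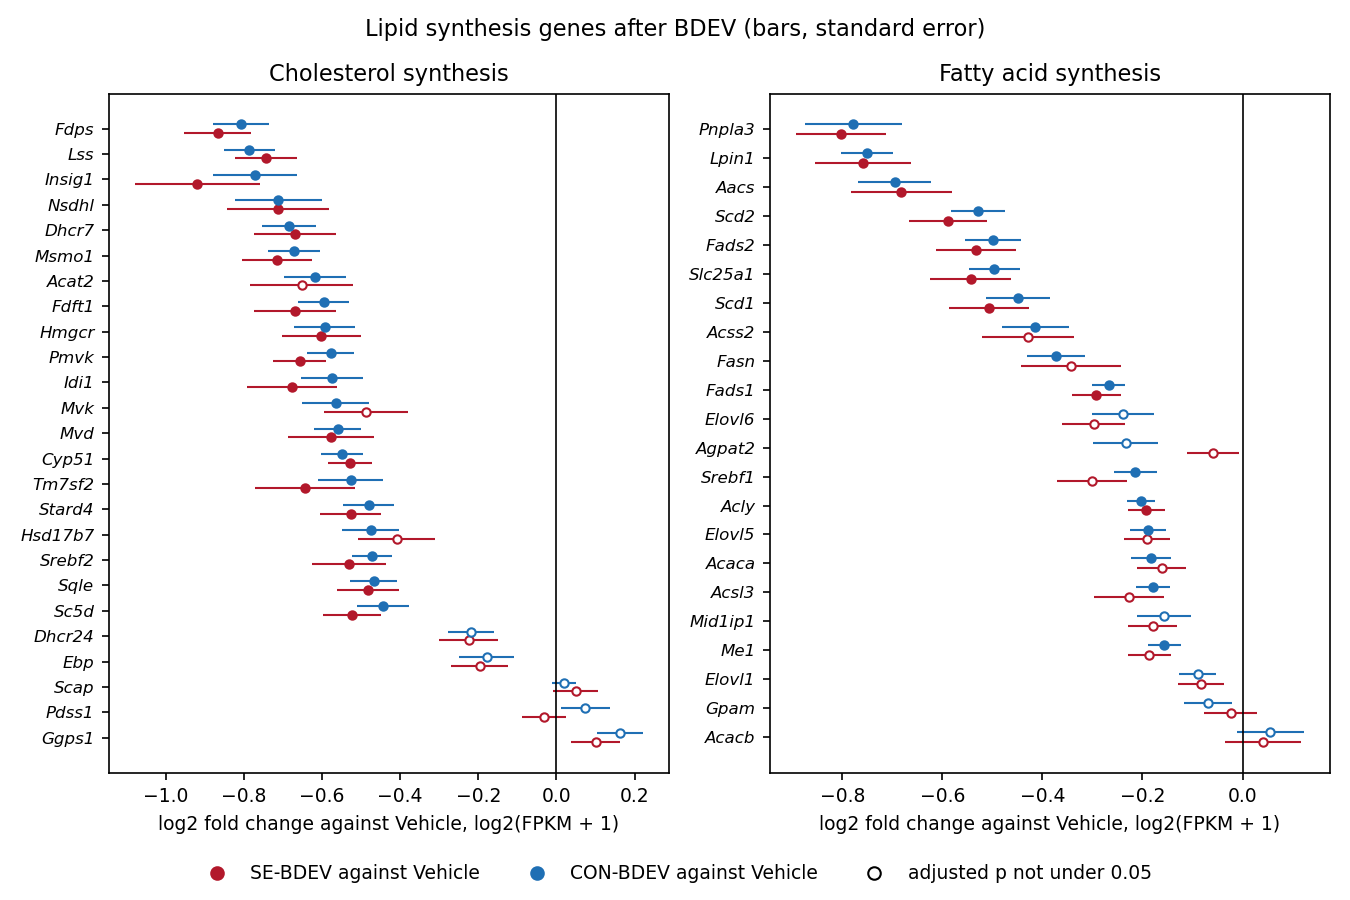
Change of genes of the cholesterol synthesis list (25 of the 26 measured) and the fatty acid synthesis list (all 22) against Vehicle, as log2 fold change on the log2(FPKM + 1) scale with its standard error; red marks SE-BDEV, blue CON-BDEV, and open symbols an adjusted p not under 0.05. Most genes of both lists lie below 0 in both groups, and Insig1 and Fdps, at −0.92 and −0.87, have the largest falls in SE-BDEV.

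In all, 104 of 11311 genes passed in SE-BDEV against Vehicle in limma, 33 that rose and 71 that fell. At the level of single tests, 1676 genes had an unadjusted p under 0.05 where 565.55 are expected by chance. Changes were small: the median absolute log2 fold change of called genes was 0.35, and 19 of them changed by at least 1.5-fold. The authors' deposited table called 140 genes, of which 64 are among the 104. The number rests on each Vehicle library: 6, 5, 7 and 16 genes passed without Vehicle replicate 1, 2, 3 or 4, against 55, 315 and 50 without SE-BDEV replicate 1, 2 or 3. In limma 0 genes passed (2021 at an unadjusted p under 0.05) when no filter on low values was applied. Of the 36 genes picked by the naming rule that passed for SE-BDEV, Fdps, Lss, Pmvk, Cyp51 and Pnpla3 passed with each of the 8 libraries left out, while 28 lost their call without any 1 of the 4 Vehicle libraries.

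Among the genes that rose with SE-BDEVs were Dbh, Ddc and Chga, members of the neuronal differentiation list. Dbh, which turns dopamine into noradrenaline (chromosome 2, 27021026 to 27038724), rose from 4.50 ± 0.425 to 6.82 ± 0.591 FPKM (SD, n = 4 each; log2 fold change 0.51 ± 0.08, standard error; limma adjusted p = 0.0158). Ddc, the decarboxylase of the step before, rose by a log2 fold change of 0.38 and the granule protein gene Chga by 0.25. The serotonin receptor subunit gene Htr3b (0.48), the actin-associated Pdlim3 (0.56) and Ablim1 (0.34), the semaphorin receptor gene Plxnd1 (0.44), Lix1 (0.39), Mrvi1 (0.35), Cpa4 (0.32) and Nrep (0.30) also rose. On the whole list of neuronal differentiation genes, 3 of 46 measured members rose and 0 fell, against 9 that rose and 8 that fell adjusted over the list alone. The median log2 fold change was −0.03 while the mean was 0.01 (camera adjusted p = 0.72).

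Other genes fell with SE-BDEVs outside lipid synthesis. The class I antigen-presenting gene H2-K1 fell from 56.0 ± 2.14 to 38.5 ± 6.23 FPKM (SD, n = 4 each; log2 fold change −0.54), and it was the 1 member of 22 interferon response genes to pass. The endosomal chloride transporter gene Clcn6 (−0.47), the 1 of 26 ion channel genes to pass, the glycolytic enzyme gene Aldoc (−0.52) and the clock-linked repressor gene Bhlhe40 (−0.42) fell as single members of their lists, as did the mitochondrial carrier gene Ucp2 (−0.37), the membrane-binding Anxa2 (−0.28), Nfkb2 (−0.26) and the transcription factor gene Klf6 (−0.21). Of 14 genes of cholesterol efflux and LXR targets, Lpcat3 (−0.32) and Npc2 (−0.24) fell and 0 rose; the median of that list was 0.03 and its mean −0.01 (camera adjusted p = 0.66). The synaptic vesicle gene Syn2 (0.23) was the 1 of 33 synapse genes to pass, and it rose.

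Cells given CON-BDEVs also expressed less of both lipid lists than cells given vehicle. Of the 26 cholesterol synthesis genes, 21 fell and 0 rose over all genes tested, against 23 that fell and 1 that rose adjusted over the list alone. The median log2 fold change was −0.56, so that the median gene fell by 32.3%. Lss fell from 29.6 ± 1.69 to 16.8 ± 1.64 FPKM (SD, n = 4 each; log2 fold change −0.79 ± 0.06, standard error; limma adjusted p = 0.000443) and Fdps from 237 ± 6.89 to 136 ± 16.3 FPKM (SD, n = 4 each; −0.81 ± 0.07, standard error; limma adjusted p = 0.000655). Cyp51 and Msmo1 followed with −0.55 and −0.67. Insig1 (−0.77) fell as well. Of the 22 fatty acid synthesis genes, 16 fell and 0 rose, 20 fell adjusted over the list alone, and the median was −0.24. Lpin1 had the smallest adjusted p of the whole comparison (12.5 ± 0.578 to 7.02 ± 0.435 FPKM, SD, n = 4 each; log2 fold change −0.75 ± 0.05, standard error; limma adjusted p = 0.000226), followed in the list by Scd2 (−0.53), Slc25a1 (−0.50) and Aacs (−0.70). Camera gave adjusted p of 2.0e-25 for the cholesterol list and 5.0e-21 for the fatty acid list. With an estimated correlation the adjusted p was 0.31 and 0.15, and in fry 0.0048 and 0.0013. All 4 CON-BDEV libraries lay below every Vehicle library in the mean of the cholesterol list, which differed by −0.49 (SD 0.13 over the 4 CON-BDEV libraries; exact permutation p = 0.0286, adjusted 0.102).

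Over all genes, 321 of 11320 passed in CON-BDEV against Vehicle in limma, 115 that rose and 206 that fell. Without adjustment, 2166 had an unadjusted p under 0.05 where 566 are expected by chance. Their median absolute log2 fold change was 0.23, and 17 changed by at least 1.5-fold. The authors' deposited table called 215 genes, of which 137 are among the 321. Counts moved by over 1.5 times without CON-BDEV replicate 1 (556), 3 (201) or 4 (156) and without Vehicle replicate 1, 2, 3 or 4 (134, 163, 140 and 161), and 176 genes passed with no filter on low values. Of 75 genes picked by the naming rule that passed for CON-BDEV, 38 passed with each of the 8 libraries left out.

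Among the genes the naming rule admits, which leaves out predicted loci, short RNA genes and entries with several names, the largest rises with CON-BDEVs were those of Adamtsl2, an extracellular matrix gene (log2 fold change 0.51 ± 0.09, standard error; limma adjusted p = 0.0118), Dbh (0.50), Pdlim3 (0.47), the thioredoxin-binding Txnip (0.47), Htr3b (0.46), Atoh8 (0.44), Ddc (0.42), Lix1 (0.42), the histamine receptor gene Hrh3 (0.38) and Gata3 (0.37), a transcription factor of sympathetic neurons. Within the list of neuronal differentiation genes 7 of 46 members rose and 5 fell, 9 rose and 8 fell adjusted over the list alone, and the camera adjusted p was 0.81. Among them Chgb (0.16) and the noradrenergic transcription factor gene Phox2a (0.25) rose while Crmp1 (−0.19), which encodes a protein of growing axons, fell. Fam129a (−0.75) and the cell cycle inhibitor gene Cdkn1a (−0.41, the 1 of 25 p53 targets to pass) fell. H2-K1 fell by a log2 fold change of 0.43, again the 1 of 22 interferon response genes to pass.

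Genes of DNA replication and ribosomal proteins moved by small amounts in both groups. Of 49 G1/S and DNA replication genes, 44 were higher in SE-BDEV than in Vehicle, with 0 past the threshold over all genes tested and 1 that rose adjusted over the list alone. In CON-BDEV 37 were higher, 5 rose over all genes tested and 15 rose adjusted over the list alone. The medians were 0.06 and 0.05 on the log2 scale, with camera adjusted p of 3.1e-05 and 2.6e-05, adjusted p of 0.20 and 0.52 with an estimated correlation, and fry adjusted p of 0.0093 and 0.0268. Dtl (0.14), Rfc4 (0.22), Mcm10 (0.16) and Exo1 (0.15) had the smallest adjusted p among them in CON-BDEV. Of 79 genes of cytosolic ribosomal proteins, 76 were lower in SE-BDEV, where 0 passed over all genes or over the list alone. In CON-BDEV 73 were lower, of which 4 fell (Rps20, Rpl28, Rpl4 and Rpl13a, from −0.13 to −0.09) and 6 fell adjusted over the list alone. Their medians were −0.07 and −0.04, with camera adjusted p of 2.4e-13 and 4.5e-07 adjusted p of 0.73 and 0.55 with an estimated correlation, and fry adjusted p of 0.163 and 0.0545. Both lists passed in camera in each comparison with every single library left out, and their directions held under median scaling. The gene calls did not hold: of the 8 fits of CON-BDEV that left out a library, Rps20 kept its call in 3, Dtl and Rpl4 in 2 and Rfc4, Mcm10, Exo1, Rpl28 and Rpl13a in 1.

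**Figure D2:**
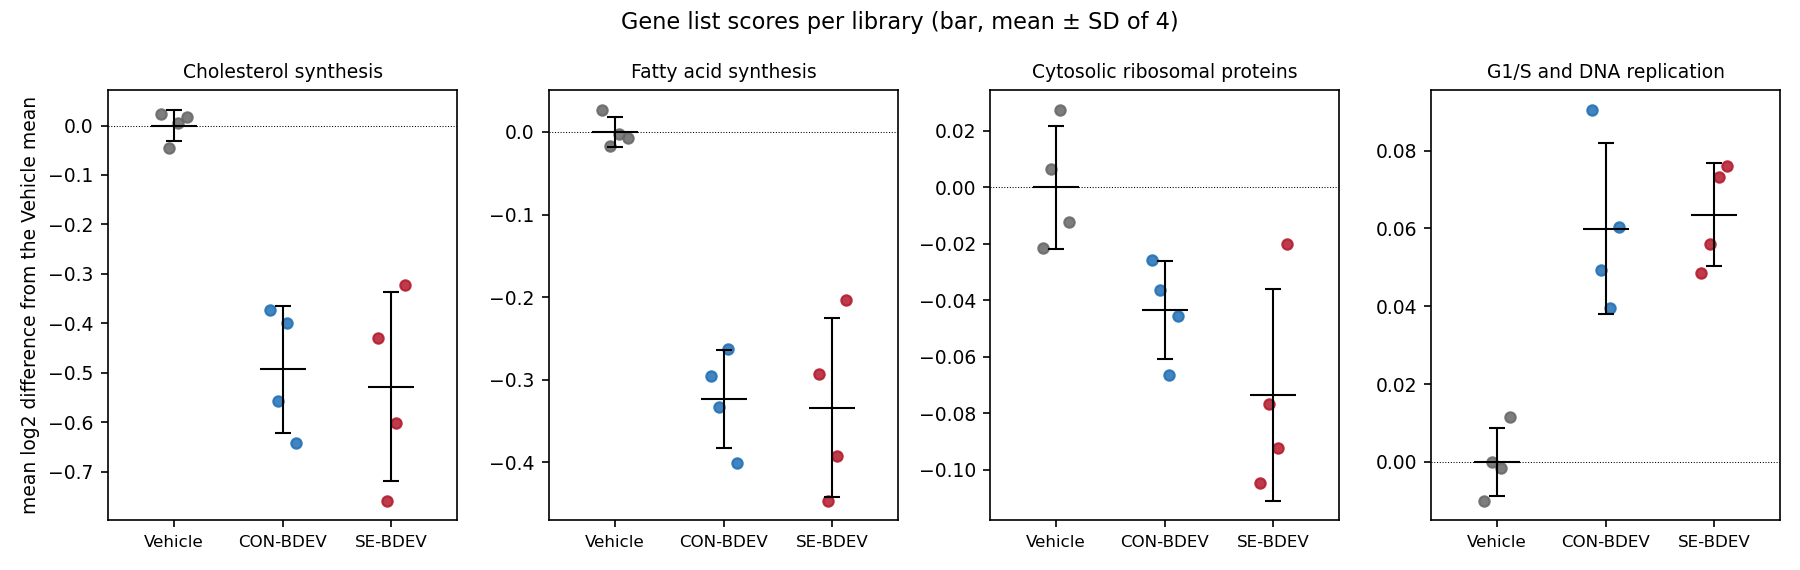
Mean log2(FPKM + 1) of 4 gene lists in each of the 12 libraries, as the difference from the mean of the Vehicle libraries; points are libraries, and lines give the mean and SD of 4. The vertical scale differs between panels: the mean differences of the cholesterol list are −0.53 and −0.49, those of the fatty acid list −0.33 and −0.32, those of the ribosomal list −0.07 and −0.04 and those of the G1/S list 0.06 in both BDEV groups.

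Further lists passed in camera with small medians and lost the call with 1 or more libraries left out. Genes of the ATF4 and unfolded protein response were lower in SE-BDEV (55 genes, median log2 fold change −0.08, 0 past the threshold, adjusted p = 0.0019; 0.84 with an estimated correlation; 0.0864 without SE-BDEV replicate 3). The mean of the list lay above that of Vehicle by 0.16 in SE-BDEV replicate 2 and below it in the other 3 SE-BDEV libraries (n = 4 each; exact permutation p = 0.371). In CON-BDEV the list did not pass (median −0.02, adjusted p = 0.0563), with 4 that fell and 1 that rose over all genes tested, against 13 and 2 adjusted over the list alone. Shmt2, Psat1 and Phgdh, of serine and glycine synthesis, and the tRNA synthetase gene Wars fell there (log2 fold changes −0.26 to −0.14), while the chaperone gene Calr rose (0.17); Phgdh was chosen after its values were seen. NRF2 targets were lower in SE-BDEV (31 genes, −0.05, 0 past, adjusted p = 0.0216; 0.73 with an estimated correlation; up to 0.0965 without SE-BDEV replicate 1 or 2 or Vehicle replicate 4). The interferon response list was lower in SE-BDEV (−0.07, adjusted p = 0.0166; 0.82 with an estimated correlation; up to 0.126 without SE-BDEV replicate 2 or 3 or Vehicle replicate 1). It was also lower in CON-BDEV (−0.06, adjusted p = 0.0283; 0.57 with an estimated correlation; up to 0.275 without CON-BDEV replicate 1 or 4 or Vehicle replicate 1 or 4). Genes of G2/M and mitosis (54 genes, 0 past in either group) had medians of −0.04 in SE-BDEV (adjusted p = 0.0166; 0.89 with an estimated correlation) and −0.05 in CON-BDEV (adjusted p = 0.0033; 0.83 with an estimated correlation). Their SE-BDEV median turned to 0.01 without SE-BDEV replicate 2 (adjusted p = 0.791) and the call was lost without Vehicle replicate 4 (0.0562), while the CON-BDEV call was lost without CON-BDEV replicate 2 (0.0944). The endocytosis list passed in SE-BDEV (45 genes, 1 fell, median −0.02, adjusted p = 0.0423; 0.84 with an estimated correlation) and lost its call without SE-BDEV replicate 2 or 3 or Vehicle replicate 2, 3 or 4 (up to 0.402).

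Both responses were set side by side over the 11278 genes tested in both. Of these, 26 rose in both, 62 fell in both and 0 of those called in both moved in opposite directions, while unchanged groups simulated against the same Vehicle libraries shared 0 rising and 0 falling genes in each of 100 simulations. Independent lists of the observed sizes would share 0.34 rising and 1.30 falling genes. The simulation leaves out any effects and the independent lists leave out the shared libraries, so neither is the overlap to be had without a shared effect. The overlap cannot exceed the SE-BDEV count, which was 6, 5, 7 and 16 without Vehicle replicate 1, 2, 3 or 4. Pdlim3, Dbh, Htr3b, Plxnd1 and Lix1 had the largest mean rises among the shared genes that the naming rule admits, and Insig1, Fdps, Pnpla3, Lss and Lpin1 the largest mean falls. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.79 and a Spearman correlation of 0.77, where unchanged groups simulated against the same Vehicle libraries gave means of 0.51 and 0.47. The covariance was 0.0108 against a simulated 0.0032, a difference of 0.0077. With each comparison given its own pair of Vehicle libraries, the Pearson correlation was 0.46 to 0.53 and the covariance 0.0074 to 0.0081 over the 6 assignments. With 2 Vehicle libraries per comparison limma called 0 genes for SE-BDEV (765 to 988 at an unadjusted p under 0.05) and therefore 0 in both, so the overlap of calls could not be checked in this way. The comparison of all 8 BDEV libraries with Vehicle called 485 of 11312 genes in limma, 216 that rose and 269 that fell.

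**Figure D3:**
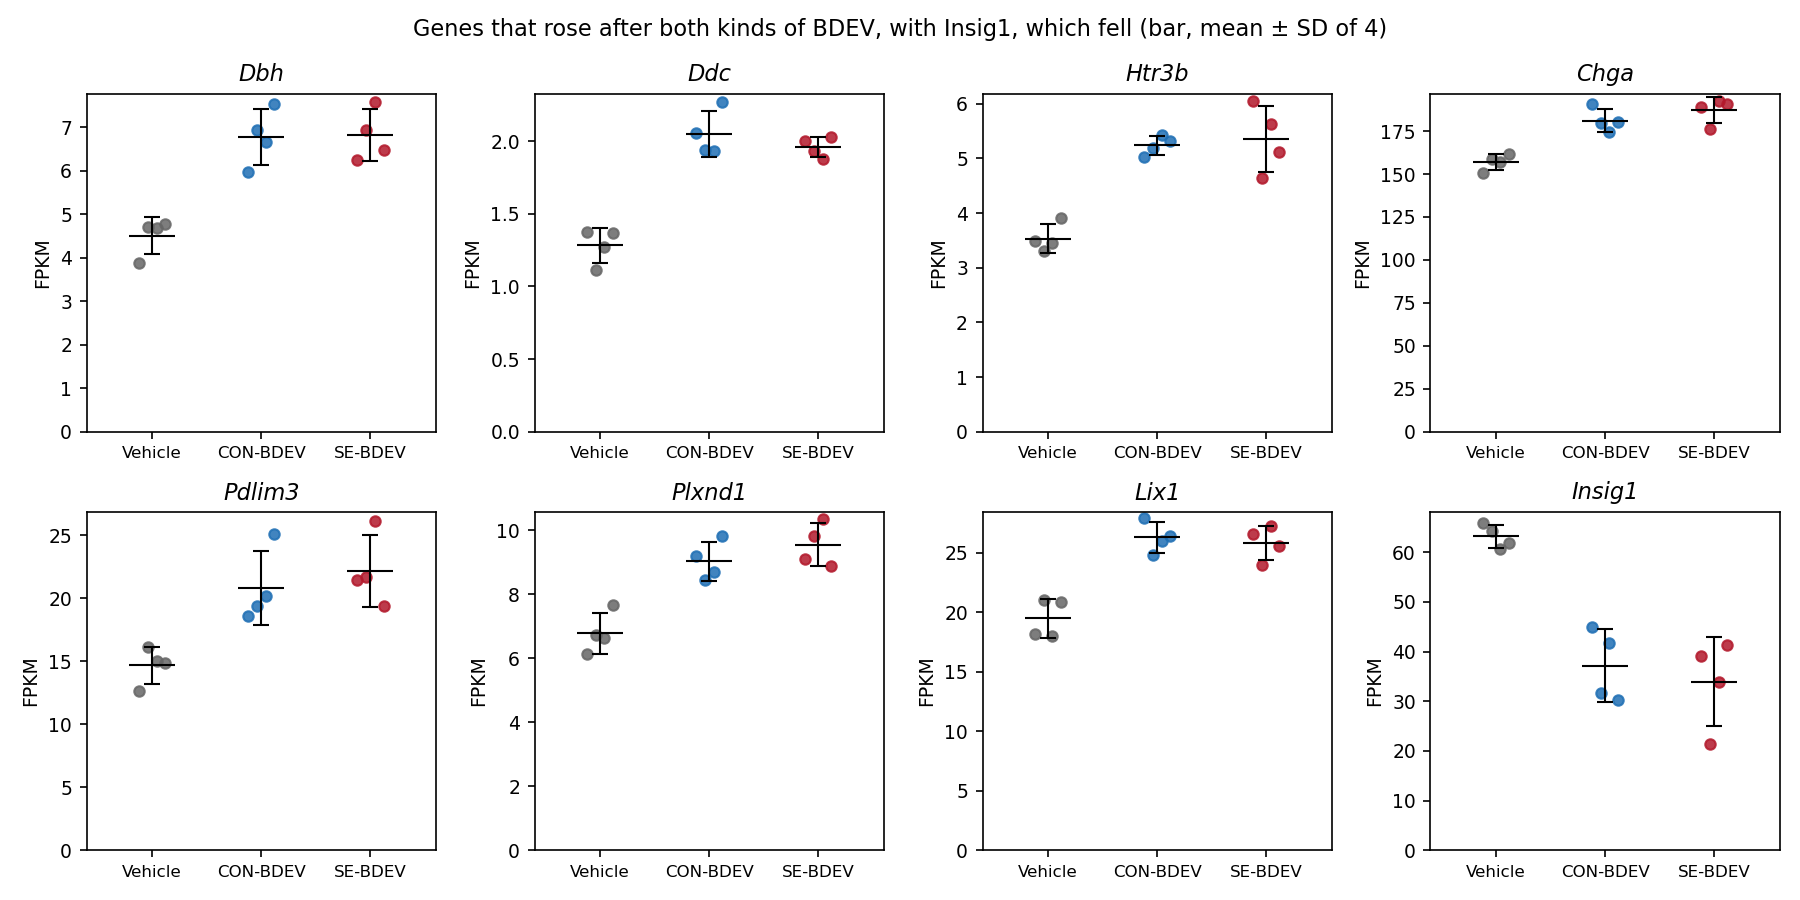
FPKM of Dbh, Ddc, Htr3b, Chga, Pdlim3, Plxnd1, Lix1 and Insig1 in each of the 12 libraries; points are libraries, and lines give the mean and SD of the 4 libraries of a group. Dbh averages 6.82 and 6.77 FPKM in SE-BDEV and CON-BDEV against 4.50 FPKM in Vehicle, and Insig1 33.9 and 37.1 against 63.2 FPKM.

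The direct comparison asked whether the response depends on the source of the vesicles. In limma, 0 of 11312 genes passed between SE-BDEV and CON-BDEV, 296 genes had an unadjusted p under 0.05 where 565.6 are expected by chance, and the smallest adjusted p was 0.643. The count was 0 in each alternative run, with 877 genes at an unadjusted p under 0.05 without SE-BDEV replicate 2; no other tool was run on this comparison. The 95% interval of the difference lay within 1.5-fold either way for 11172 genes (98.8%) and within 2-fold for 11282 genes (99.7%). For 334 of the 337 genes called in either comparison with Vehicle it lay within 1.5-fold. This bound is wide beside the responses themselves: 19 of 104 and 17 of 321 called genes changed by at least 1.5-fold against Vehicle. A response missing from 1 group could thus lie within it for many of them. The intervals may also be too narrow, since each gene had 1 spread over all 12 libraries. Vehicle, which was not compared here, varied least (median SD 0.0565, against 0.0898 in SE-BDEV and 0.0739 in CON-BDEV). Folds were on the log2(FPKM + 1) scale, so for genes with low values the bound on FPKM itself is wider. Over the 337 genes the median absolute difference was 0.03 and the median half-width of the interval 0.11 on the log2 scale. The mean of the cholesterol list differed between SE-BDEV and CON-BDEV by −0.04 on the log2 scale (95% interval −0.32 to 0.25, n = 4 each; exact permutation p = 0.80) and that of the fatty acid list by −0.01 (−0.16 to 0.14, n = 4 each; exact permutation p = 0.914).

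None of the genes with the smallest p in this comparison passed. Alg14, which takes part in the first steps of N-glycan assembly (chromosome 3, 120994734 to 121064929), was at 23.9 ± 0.662 FPKM in SE-BDEV and 19.2 ± 1.49 FPKM in CON-BDEV, with 20.1 ± 0.941 FPKM in Vehicle (SD, n = 4 each; log2 fold change 0.30 ± 0.05, standard error; limma unadjusted p = 5.7e-05, adjusted p = 0.643). Values were higher in SE-BDEV also for Rhox2f, Pcca, Clybl and Lgals9 (log2 fold changes 0.17 to 0.26) and lower for Ndufa12, Myeov2, Ssr4, Prorsd1 and Nat6 (−0.24 to −0.15), each with a limma adjusted p of 1. Of the gene lists, ribosomal proteins (59 of 79 lower in SE-BDEV, median −0.02, adjusted p = 0.000104), NRF2 targets (24 of 31 lower, −0.03, adjusted p = 0.0350) and nuclear genes of oxidative phosphorylation (46 of 75 lower, −0.01, adjusted p = 0.0350) passed in camera. The oxidative phosphorylation median was 0.0036 without CON-BDEV replicate 1. With an estimated correlation the adjusted p of all 3 was 0.98, and in fry 0.96. The ribosomal list lost its call without SE-BDEV replicate 1 (0.0886), the NRF2 list without SE-BDEV replicate 1 or 2 or CON-BDEV replicate 2 or 4 (up to 0.378), and the oxidative phosphorylation list without SE-BDEV replicate 1, 2 or 3 or CON-BDEV replicate 1 or 4 (up to 0.726).

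Marker genes of other brain cells were measured because the vesicles came from brain. In SE-BDEV against Vehicle, the astrocyte (7 genes measured), oligodendrocyte (7), endothelial (6) and forebrain neuron (13) lists had camera adjusted p of 0.73, 0.63, 0.92 and 0.59, and in CON-BDEV against Vehicle (12 forebrain neuron genes) 0.77, 0.99, 0.76 and 0.19. Between SE-BDEV and CON-BDEV the adjusted p were 0.84, 0.67, 0.18 and 0.84. Of all these markers, Aldoc fell in both groups and Sparcl1 rose in CON-BDEV (log2 fold change 0.32; limma adjusted p = 0.0428); with each of the 8 libraries left out in turn, the Sparcl1 call was kept in 1 fit and that of Aldoc in 2 for SE-BDEV and in 1 for CON-BDEV. Adjusted over the list alone, up to 3 members of the astrocyte, endothelial and forebrain neuron lists passed in 1 direction and 0 oligodendrocyte markers did. On the first 2 principal components, which held 20.8% and 19.6% of the variance over the 12 libraries, SE-BDEV replicate 3 lay apart on the first and SE-BDEV replicate 2 on the second. Without these 2 libraries 154 genes passed for SE-BDEV against Vehicle, 77 of them among the 104.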

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

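Of the tests in this part, those of library scaling, of GC content and length for the fatty acid genes, of the handling of Vehicle, of the spread between SE-BDEV libraries and of other splits for SE-BDEV against CON-BDEV were chosen only after the result was seen.

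The fall of sterol and fatty acid synthesis genes was present in both BDEV groups against Vehicle, with median log2 fold changes of −0.59 and −0.56 for the cholesterol list and −0.29 and −0.24 for the fatty acid list. Library scaling was argued against as the whole cause, since the median log2 fold change of all genes tested was 0.009 (SE-BDEV) and 0.004 (CON-BDEV) without rescaling. After quantile normalization, which for that reason could move the lists little, the cholesterol median lay −0.594 (SE-BDEV) and −0.569 (CON-BDEV) from that of all genes. The fatty acid median lay −0.297 and −0.244 from it. A trend on GC content or transcript length was argued against as well, since its removal left cholesterol medians of −0.583 and −0.557 over all 26 members and fatty acid medians of −0.30 and −0.231 over all 22. Handling of the Vehicle libraries apart from the others cannot be told apart from treatment, because 0 of the 4 Vehicle libraries carry a number among those of the BDEV libraries (1 to 8, against 9 to 12 for Vehicle). A shared response to brain vesicles of either kind may also account for the fall and stays a hypothesis, as no other vesicle was among the groups.

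Fewer genes passed for SE-BDEV (104) than for CON-BDEV (321), while limma called 0 genes between these groups (296 at an unadjusted p under 0.05). Over the 485 genes called for all 8 BDEV libraries together, the SE-BDEV change was 1.03 times the CON-BDEV change. With each library left out it was 0.968 to 1.13 times. That argues against a smaller SE-BDEV response in these genes only. They were called in the same libraries with both kinds of BDEV as 1 group, which favours genes with equal changes. A smaller response in other genes stays open. A larger spread between the SE-BDEV libraries is the candidate explanation that the values favour, since the median within-group SD was 1.21 times that of CON-BDEV and 1 shared estimate of the spread gave 171 genes for SE-BDEV and 133 for CON-BDEV. Both counts depend on single libraries: 315, 55 and 50 genes passed without SE-BDEV replicate 2, 1 or 3 and 5 to 16 without any 1 Vehicle library, and for CON-BDEV 556, 201 and 156 without replicate 1, 3 or 4 and 134 to 163 without any 1 Vehicle library. Why the SE-BDEV libraries spread more was not tested.

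Other splits of the 8 libraries argued against chance for both counts against Vehicle without excluding it. Only 1 of 35 splits, the real one, gave as many as 104 genes (highest other 1), and 1 of 35 gave as many as 321 (highest other 1). A share of 1 in 35 is the smallest possible. The other splits mix BDEV and Vehicle libraries, so a difference between the groups widens their spread and lowers their counts. The splits cannot tell treatment from separate handling of Vehicle. Between SE-BDEV and CON-BDEV the count of 0 in limma is reached by any split and decides nothing. At an unadjusted p under 0.05, where the real split had 296 genes, 35 of 35 splits had at least as many (highest other 2546), so the splits do not argue against chance there. Of the other splits, 8 called genes, up to 391, which points to a structure of these samples that the treatment groups do not follow.

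Gfap, the intermediate filament gene of astrocytes, was chosen after its values were seen and lay below the levels tested. It stood at 0.0518, 0.1327, 0.0561 and 0.0705 FPKM in the SE-BDEV libraries, at 0.0265, 0, 0.0261 and 0 FPKM in CON-BDEV and at 0, 0, 0 and 0.0254 FPKM in Vehicle. These are about 11.6, 1.97 and 1.01 estimated fragments per group in sum (SE-BDEV against CON-BDEV, n = 4 each, two-sided exact permutation p = 0.0286, the smallest possible).

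Whether chance among rare markers accounts for the Gfap values is not settled. Of 91 low marker genes of 6 cell type lists, Gfap was the 1 gene with all SE-BDEV libraries highest. In CON-BDEV 0 genes had all libraries highest. For Vehicle it was 1 gene, Aldh1l1 (also chosen after its values were seen), where 0.184 genes per group are expected. A gene highest in Vehicle may reflect the difference of Vehicle from both BDEV groups, so it is no clean measure of chance. Brain RNA carried over with the vesicles cannot be told apart from chance. The summed fragments of 87 other low markers in SE-BDEV were 0.929 times those in Vehicle, under the bound of 1.2 set beforehand, but that bound was wrong, because these genes average 473 fragments per SE-BDEV library and would hide an addition as small as that of Gfap. The status epilepticus named by the design stays open as a biological difference and was not tested as the cause.

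Several genes had 1 library far from the other 3 of its group, given here as the gap to the nearest library over the range of the group on log2(FPKM + 1). In Vehicle these were Lpin1 (replicate 1, 0.835), Klf6 (replicate 3, 0.884), Dbh (replicate 1, 0.901), Hand2 (replicate 1, 0.851) and Gfap (replicate 4, 1, with the others at 0). In SE-BDEV they were Aldoc (replicate 3, 0.878), Clybl (replicate 4, 0.837), Abca1 (replicate 2, 0.935) and Calr (replicate 2, 0.900). In CON-BDEV they were Ucp2 (replicate 4, 0.920), Alg14 (replicate 1, 0.885), Lgals9 (replicate 4, 0.931), Prorsd1 (replicate 1, 0.952), Rpl4 (replicate 2, 0.923) and Rpl13a (replicate 3, 0.849). The mean of the G2/M list stood apart in SE-BDEV replicate 2 (0.954; −0.20 on the log2 scale relative to Vehicle, against 0.01 to 0.02 in the other 3) and in Vehicle replicate 4 (0.846). In all, 17 of 282 groups of 4 stood out, where chance gives about 14.1 at 1 in 20.

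Between SE-BDEV and CON-BDEV, 3 gene lists differed in camera: ribosomal proteins (adjusted p = 0.000104), NRF2 targets (adjusted p = 0.0350) and nuclear oxidative phosphorylation genes (adjusted p = 0.0350). With an estimated correlation the adjusted p of each was 0.98. The first call was lost without SE-BDEV replicate 1 (0.0886), the second without SE-BDEV replicate 1 or 2 or CON-BDEV replicate 2 or 4 (up to 0.378), and the third without SE-BDEV replicate 1, 2 or 3 or CON-BDEV replicate 1 or 4 (up to 0.726). Prorsd1 lay below the Vehicle mean in every SE-BDEV library and above it in every CON-BDEV library, a difference of −0.215 on the log2 scale. The opposite directions were not tested as such, the gene was named for its small p, and its limma adjusted p between the groups was 1.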

How the results depend on the processing

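The fit without the 2 SE-BDEV libraries that lie apart and the fit of all BDEV libraries against Vehicle were chosen after seeing the data. No gene called against Vehicle in limma changed direction in any alternative fit. The SE-BDEV count of 104 stayed within 1.5 times with a pseudocount of 0.1 (100), a minimum of 5 FPKM (138), median (137) or quantile scaling (133), robust settings (108), no variance trend (73), the authors' deposited calls (140) and without the 2 libraries apart (154). It was 0 in limma with no filter on low values, where 17444 genes were tested (2021 at an unadjusted p under 0.05, smallest adjusted p 0.0554), 245 with library weights, 171 with all 3 groups in 1 fit and 19 with a minimum change of 1.5-fold. The CON-BDEV count of 321 was 325, 347, 326, 310 and 348 under the first 5 of these settings and 215 in the authors' deposited calls. It moved to 183 without the trend, 176 with no filter, 542 with weights, 133 with all groups in 1 fit and 17 with a minimum change of 1.5-fold. Asking for a minimum change lowers a count by construction. The cause of the other moves, that with no filter on low values among them, was not tested. With each library left out the count ranged from 5 (without Vehicle replicate 2) to 315 (without SE-BDEV replicate 2) for SE-BDEV and from 134 (without Vehicle replicate 1) to 556 (without CON-BDEV replicate 1) for CON-BDEV. For all BDEV libraries it went from 485 to between 160 (without Vehicle replicate 1) and 539 (without SE-BDEV replicate 2), with 250, 217 and 232 without Vehicle replicate 2, 3 or 4 and 289 without CON-BDEV replicate 4. Fewer libraries lower the power of a fit, but counts moved both ways, so this alone does not set them. The cause of the moves was not tested. Between SE-BDEV and CON-BDEV limma called 0 genes in every alternative, with 218 to 877 at an unadjusted p under 0.05.

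Whether the replicate numbers pair the samples is not settled. Deviations of SE-BDEV and CON-BDEV libraries of the same number correlated across genes with r of 0.20, 0.30, −0.07 and −0.12. SE-BDEV replicates 1 and 2 correlated best with the CON-BDEV library of their own number (at most 0.10 and 0.03 with others), and replicates 3 and 4 did not. By library number the SE-BDEV and CON-BDEV libraries alternate, and those of the same replicate number are neighbours. With the replicate number as a block 48 genes passed for SE-BDEV, 135 for CON-BDEV and, in limma, 0 between them (312 at an unadjusted p under 0.05). That block also tied in the Vehicle libraries by number. The BDEV libraries were not fitted as pairs by themselves, so the 0 does not test a pairing between the BDEV groups.

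Camera called 9 lists for SE-BDEV, 6 for CON-BDEV and 3 between them, and with an estimated correlation 0, 0 and 0. The adjusted p of the cholesterol list was then 0.20 (SE-BDEV) and 0.306 (CON-BDEV) and that of the fatty acid list 0.20 and 0.152. Fry, which tests a list by itself, called 3, 4 and 0. With each library left out camera called 6 to 10, 5 to 9 and, between the BDEV groups, 0 (without SE-BDEV replicate 1) to 6 (without SE-BDEV replicate 4). The G2/M list in SE-BDEV had adjusted p from 0.000355 to 0.791 over the libraries left out. Its direction turned without SE-BDEV replicate 2 (0.791) and without the 2 libraries apart (0.960), and the cause was not tested.

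With 2 Vehicle libraries for each comparison the shared calls went from 88 to 0 in each of 6 assignments, as limma called 0 genes for SE-BDEV (765 to 988 at an unadjusted p under 0.05), and Pearson's r from 0.79 to as low as 0.461. Fewer samples and no shared control act on both. The covariance was 0.0171 with a pseudocount of 0.1, the cause of which was not tested.

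With a library left out, single named genes kept their side of the threshold in 429 of 608 values for SE-BDEV (156 lost it, 23 passed anew) and 419 of 608 for CON-BDEV (188 lost it, 1 passed anew). Under the other settings 720 of 829 and 617 of 753 did. Genes under a mean of 1 FPKM entered only the fits with no filter.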

Other observations

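Of the tests in this part, those of LXR targets, of neuronal differentiation genes and of the list means per library were chosen only after the result was seen, as was the reading of all other genes near the floor. The random sets of rare genes were set before their result but after Gfap had been noticed.

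In the comparison of all 8 BDEV libraries with Vehicle, single members of the neuronal differentiation list moved both ways. Dbh (log2 fold change 0.50 ± 0.06, standard error), Ddc (0.40 ± 0.06), Gata3 (0.31 ± 0.06), Phox2a (0.21 ± 0.04) and Hand2 (0.20 ± 0.04) rose, the last 3 being transcription factors of sympathetic neurons. The granule genes Chga (0.23 ± 0.03) and Chgb (0.17 ± 0.03) rose with them. Tubb2b, a tubulin (−0.28 ± 0.07), Stmn2 (−0.20 ± 0.04) and Stmn3 (−0.10 ± 0.03), which bind tubulin, and Crmp1 (−0.19 ± 0.03) and Dpysl2 (−0.17 ± 0.04), of growing axons, fell, as did the granule gene Scg2 (−0.13 ± 0.03). Limma adjusted p ran from 0.000623 (Dbh) to 0.0487 (Stmn3). Hand2, Tubb2b, Stmn2, Stmn3, Dpysl2 and Scg2 were chosen after their values were seen. A general rise of neuronal differentiation was argued against as an explanation, since the median of the 46 measured genes of that list was −0.0274, with 7 that rose and 6 that fell. No narrower group of these genes was tested.

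Small shifts that failed correction were seen in other lists. For the permutation tests this failure carries little weight, since their smallest possible p passes only where many lists reach it together. The mean of 33 hypoxia and glycolysis genes lay below every Vehicle library in 4 of 4 SE-BDEV and 4 of 4 CON-BDEV libraries, by −0.05 in each (SD 0.0256 and 0.0205, n = 4 each; two-sided exact permutation p = 0.0286, adjusted 0.131 and 0.102). The mean of 26 genes of fatty acid oxidation did so as well, by −0.05 and −0.06 (SD 0.0494 and 0.0286, n = 4 each; exact permutation p = 0.0286, adjusted 0.131 and 0.102). For 33 apoptosis regulators the mean also lay below every Vehicle library in 4 of 4 libraries of each BDEV group. It did so by −0.02 in each (SD 0.0218 and 0.0118, exact permutation p = 0.0286, adjusted 0.131 and 0.102). Replication-dependent histone genes had medians of 0.28 (16 genes, camera adjusted p = 0.0762) in SE-BDEV and 0.12 (19 genes, camera adjusted p = 0.0639) in CON-BDEV, with 1 that rose adjusted over the list alone in each.

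Sterol genes that fall together could follow from activation of LXR, a nuclear receptor that answers to oxidised sterols, or from sterol brought into the cell. The LXR list had medians of 0.0256 (SE-BDEV) and 0.0139 (CON-BDEV), which decide nothing because its 14 measured members went both ways (9 higher and 5 lower in SE-BDEV, 8 and 6 in CON-BDEV). Past the threshold, 2 members (Lpcat3 and Npc2) fell and 0 rose in SE-BDEV, and both also fell in CON-BDEV. Scarb1 fell in CON-BDEV as well, from a mean of 60.5 FPKM in Vehicle to 53.5 FPKM. Its call was kept in 3 of the 8 fits that left out a library. The mean of the list lay below every Vehicle library in 4 of 4 CON-BDEV libraries, by −0.02 (two-sided exact permutation p = 0.0286, adjusted 0.102). Abca1, which LXR raises, was higher than in every Vehicle library in 8 of 8 BDEV libraries, with log2 fold changes of 0.19 and 0.18 that did not pass (limma adjusted p = 0.415 and 0.154). Much of its SE-BDEV change came from replicate 2, at 3.69 FPKM, while replicates 1, 3 and 4 stood at 2.47, 2.51 and 2.54 FPKM. Srebf1, which both LXR and SREBP raise, had −0.30 in SE-BDEV (limma adjusted p = 0.0788) and fell by 0.21 on the log2 scale in CON-BDEV (limma adjusted p = 0.0252); both genes were chosen after their values were seen. A rise of Srebf1 through LXR would be expected to raise SREBP1 targets. The list of fatty acid synthesis and SREBP1 targets instead fell, with median log2 fold changes of −0.29 (SE-BDEV) and −0.24 (CON-BDEV). That argues against LXR activation alone as the cause of the joint fall of both lipid lists. LXR activation beside another cause stays open, as does delivery of sterol by the vesicles, for which the design has no test.

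Marker genes of other brain cells with under 1 estimated fragment per Vehicle library were summed, without Gfap, to ask whether rare brain RNA differed between the BDEV groups. The 40 such markers had 18.5 ± 0.863 fragments per SE-BDEV library and 11.5 ± 1.5 per CON-BDEV library (SD, n = 4 each; ranges 17.5 to 19.6 and 9.69 to 13.2; two-sided exact permutation p = 0.0286, the smallest possible). Of these, 26 were higher and 10 lower in SE-BDEV. Scaled to depth the ratio was 1.58, at the 97.57th percentile of 10000 random sets of as many of the 2668 other genes near the floor, whose middle 95% ran from 0.627 to 1.57. All those other genes together had a ratio of 0.996 (n = 4 each; exact permutation p = 0.857). That argues against a general rise of rare genes as the cause. The markers' ratio lies above the upper bound of the random sets by less than the error of the draws, so chance in which genes form the set stays open. Vehicle had 6.95 ± 3.00 fragments (SD, n = 4), but the genes were selected for low values there, and the other genes near the floor were 1.72 times higher in CON-BDEV than in Vehicle. Carry-over of brain RNA with the SE-BDEVs is a hypothesis that may be tested with deeper libraries.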
